A study of Mus musculus with 36 samples.

How the data were processed

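RNA of 36 samples was measured on Affymetrix mouse whole-genome expression arrays. The samples were 6 cell populations sorted from mouse thymus at 3 ages, with 2 arrays per population and age. Per the series' design text, thymi were digested with enzymes, the cells were purified by flow cytometry, and the RNA was amplified, labelled and hybridised. Per the labels, RNA was extracted with Trizol and biotinylated cRNA was made by the manufacturer's protocol. Per the series' design text, the raw arrays were normalised with Gene Expression Commons, and the submitters' processing notes name GCRMA. Its version and its settings are not given in the sources used here.

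The deposited values are log2 signals per probe set, on a common scale for all arrays. The log base is not stated in the labels and was read from the range of the values. The arrays' medians lay between 5.61 and 5.74, their distributions were not identical, and the values were not centred per gene, as tested on the table. The deposited values were used with no further scaling. The table held 45101 probe sets, of which 64 were controls, 34945 had 1 gene symbol, 932 had several and 9160 had none. Control probe sets and those without a single symbol were left out. Each of the 18193 remaining genes was represented by its probe set with the highest mean, and 14497 genes were tested, those above the pooled median of all values (5.65) in at least 2 arrays.

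Groups were taken from the labels. A linear model with 1 mean for each of the 18 groups was fitted to all arrays with limma 3.58.1 in R 4.3.3, with 18 residual degrees of freedom, moderated with an intensity trend. Each population was compared with the mean of the other 5, and mTEChi with mTEClo, cTEC with the mean of both mTEC populations, and Sirpa+ with Sirpa− DC, with ages weighted equally. Within each population, 3 and 6 months were compared with 1 month. The mean of the 6 populations was compared between all 3 ages, the change from 1 to 6 months was compared between the means of the 3 epithelial and the 2 DC populations, and a moderated F-test over 10 contrasts tested whether changes with age differed between populations. All tests were two-sided, with Benjamini-Hochberg adjustment over the genes of a comparison. A gene was called at an adjusted p under 0.05, and in comparisons of populations also at a difference of at least 2-fold. A comparison within a population is 2 arrays against 2, with the spread taken from all groups.

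There were 35 gene lists with 583 genes, of which 548 had a probe set. They covered marker genes of the sorted and of other cell types, tissue antigens, and cellular processes. Lists were tested with camera from limma at a preset correlation between genes of 0.01 and again with an estimated correlation, with adjustment over the lists of a comparison, and with fry. A preset correlation takes genes of a list as nearly independent, so the estimated one is given beside it. The correlation between genes is estimated from the residuals of the same arrays. Dim genes of a list that were not tested were left out of its count.

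Named genes followed a rule. For each population against the others, they were taken from the top of the 15 largest folds among called genes with every array of the population above every other array. For pairs of populations they were taken from the 10, and for ages within a population from the 5, largest changes each way among called genes without overlap of the arrays compared, so that every array showed the direction. For the mean of the 6 populations they were taken from the 10 largest each way with the same direction in all 6. From each list, up to 4 called members with the largest change could be named. The comparisons, thresholds, lists, naming rule and alternatives were chosen before the data were examined, except for 2 contrasts and 1 alternative named as such, the lists in the means of the epithelial and DC populations other than E2F targets and inflammatory mediators, and the scaling of the lists. Gm4951 was named outside the rule, after its values were seen.

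RNA quality was read from the Gapdh and Actb control probe sets, as the mean of the 3′ minus the 5′ log2 signal in an array, and thymocyte RNA from the mean of the thymocyte markers. The correlation of the residuals of arrays sharing an age and a replicate number was computed to ask whether the numbers pair the samples. Alternatives were other probe set filters, the mean of all probe sets of a gene, quantile normalization, equal array medians, other variance models, array weights, a fit of only the groups compared, replicate blocks, the thymocyte and 3′ minus 5′ values as covariates, a 4-fold threshold for populations with a 2-fold threshold for ages, leaving out each array in turn in 36 fits, and a fit without the 6 fibroblast arrays. The least favourable array was taken for named genes. Labels were reassigned in 100 splits, the real one included, of the arrays within each age or within each population. The intervals of the dilution test came from resampling its genes with replacement, chosen after the data were seen. The model was tested on simulated data with 200 changed genes. It recovered 97 at a log2 change of 1 and 195 at a change of 2 in a comparison of 2 arrays with 2, and 193 and 200 in the mean of the 6 populations, with 0 in the wrong direction and 5 to 12 unchanged genes called in those comparisons. The simulated noise was independent between arrays, with 1 SD per gene for all groups. In the real data the SD of the difference between the 2 arrays of a group went from 0.235 (Sirpa+ DC, 6 months) to 0.619 (fibroblasts, 6 months). The simulation therefore does not cover unequal spread or shared mice. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with numpy 2.4.6 and pandas 2.3.3, and random and weighted fits used statmod 1.5.0.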

Results

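Gene expression was measured on 36 microarrays of RNA from 6 cell populations sorted from the thymus of male C57BL/6J mice. The populations were cortical thymic epithelial cells (cTEC), medullary thymic epithelial cells with low or high CD80 and MHC class II (mTEClo and mTEChi), Sirpa-negative and Sirpa-positive dendritic cells (Sirpa− DC and Sirpa+ DC), and fibroblasts. Each was sorted from mice of 3 ages (1, 3 or 6 months), with 2 arrays per age, giving 18 groups of 2, 6 arrays per population and 12 per age. The log2 median of an array lay between 5.61 and 5.74, and the number of arrays limits the precision. The labels name 1 mouse per sample, while the series' design text names 2 mice per age, so the 12 arrays of an age may come from 2 mice. If they do, the p-values measure only the spread between samples of those animals.

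Each of the 36 arrays was most similar to an array of its own population, and in 11 of the 18 groups the 2 arrays were each other's closest match. The correlation between the 2 arrays of a group, across genes, ranged from 0.949 in mTEChi at 6 months to 0.994 in Sirpa+ DC at 6 months. The first 2 principal components held 44.6% and 21.8% of the variance. Genes that define the populations followed the labels. Aire, the regulator of tissue antigen expression in the medulla, averaged log2 11.19 ± 0.47 (SD, n = 6) in mTEChi and 7.59 ± 1.06 in mTEClo, against 5.63 to 6.66 in the other populations. Psmb11, the thymoproteasome subunit of the cortex, averaged 10.96 ± 0.77 in cTEC and 4.75 to 6.80 elsewhere. Foxn1, the master regulator of thymic epithelium, averaged 9.37 in cTEC, 8.40 in mTEClo and 9.64 in mTEChi, with 3.82 to 4.13 in the other populations. Fezf2, a second regulator of medullary antigens, averaged 11.54 in mTEChi, 10.05 in mTEClo and 7.13 in cTEC. Itgax, which encodes CD11c, averaged 10.74 and 11.16 in the DC populations and 5.29 to 5.91 in the others. Pdgfra, a mesenchymal receptor, averaged 10.62 ± 1.34 in fibroblasts and 5.03 to 6.48 in the others. Sirpa averaged 10.21 in Sirpa+ DC and 7.03 ± 0.91 in Sirpa− DC. Epcam averaged 10.75 to 11.80 in the epithelial populations, but 10.13 in Sirpa+ DC and 8.46 in Sirpa− DC. The transcription factor gene E2f3 averaged 7.07 to 8.03 across the 6 populations.

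**Figure D1:**
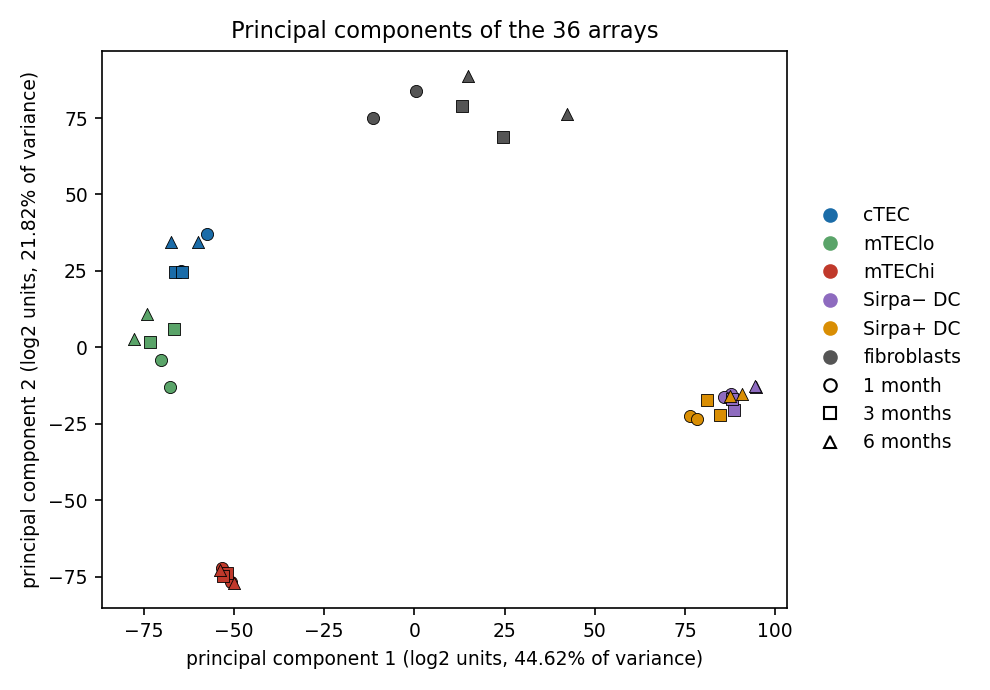
Each point is 1 of the 36 arrays, placed by its first 2 principal components (44.6% and 21.8% of the variance of the log2 values), with colour for the population and shape for the age. The epithelial populations lie apart from the DC on the first component, while the Sirpa+ DC arrays at 6 months lie among the Sirpa− DC arrays and the fibroblast arrays are spread out.

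The first comparisons asked which genes set each population apart from the other 5, with all ages weighted equally. In cTEC, 1411 genes were at least 2-fold higher, and 190 of these were above all other arrays in each of the 6 cTEC arrays. The largest differences were in Scn1a, a sodium channel subunit (40.3-fold, log2 5.33 ± 0.11 SE, n = 6 against 30, adjusted p = 7.65e-22), and Psmb11 (38.8-fold, 5.28 ± 0.17, adjusted p = 2.88e-18). Fmod, a collagen-binding proteoglycan, Prss16, the thymus-specific serine protease, and Ccl25, the chemokine bound by CCR9 on thymocytes, were 37.0-fold, 35.4-fold and 27.9-fold higher. Of 14 cTEC markers, 13 were higher and 0 lower (mean log2 3.57; camera adjusted p = 9.1e-13), among them Tbata at 5.10 ± 0.23, and adjusted p = 0.00951 with an estimated correlation. Of 35 matrix genes, 15 were higher and 3 lower (adjusted p = 0.0056), such as Ogn (3.36 ± 0.23), Tnc (3.07 ± 0.19) and the laminin chain gene Lamb1 (2.76 ± 0.22). This call was lost with an adjusted p = 0.662 with an estimated correlation. Genes of mitosis were lower in cTEC, 28 of 31 with 0 higher (mean −1.32; adjusted p = 9.1e-13), such as the spindle checkpoint kinase Bub1 (−1.99 ± 0.15) and Aurkb (−1.90 ± 0.17), with adjusted p = 0.148 with an estimated correlation. Of 15 thymocyte markers, 2 were higher and 0 lower (mean 0.53; adjusted p = 0.16), Rag1 by 1.43 ± 0.42 and Dntt by 1.14 ± 0.29, which act in receptor rearrangement. For the lists given here for the 6 populations and the 3 pairwise comparisons, the counts adjusted over the list alone equalled those adjusted over all genes.

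In mTEClo, 1365 genes were at least 2-fold higher than in the other 5 populations, 99 of them in each array above all others. Among these 99, Crp, the acute-phase C-reactive protein, led with 34.7-fold (log2 5.12 ± 0.17 SE, n = 6 against 30, adjusted p = 3.7e-18). Also among the 99, Krt14, a keratin of basal epithelium, followed with 29.0-fold (4.86 ± 0.14, adjusted p = 4.89e-19), then Clca3a1 with 22.8-fold and Slitrk4, a neuronal membrane protein, with 22.4-fold. Of 9 mTEClo markers, 7 were higher and 0 lower (mean 2.80; camera adjusted p = 1.58e-07, and 0.0489 with an estimated correlation). These included Krt17 (4.70 ± 0.12), the basal regulator Trp63 (4.10 ± 0.16) and Krt5 (3.89 ± 0.15). Interferon-induced genes were higher for 9 of 21 and lower for 0 (mean 1.03; adjusted p = 9.39e-08), with Cxcl10 at 2.30 ± 0.19 and Ifit3 at 2.19 ± 0.11. That call was lost, adjusted p = 0.122 with an estimated correlation. Matrix genes were higher for 15 of 35 and lower for 3 (adjusted p = 0.00207), such as the collagen VI chain Col6a1 (3.34 ± 0.20), but adjusted p = 0.568 with an estimated correlation. Mitosis genes were lower for 18 of 31 (mean −1.11; adjusted p = 3.14e-13), with the centromere histone Cenpa at −2.20 ± 0.15, and adjusted p = 0.162 with an estimated correlation.

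In mTEChi, 2015 genes were at least 2-fold higher than in the other 5 populations, and 904 of them were above all others in each array. The leading genes belong to tissues outside the thymus. Calcb, a neuropeptide, was 103-fold higher (log2 6.69 ± 0.30 SE, n = 6 against 30, adjusted p = 5.25e-16), Hbb-y, an embryonic globin, 101-fold, and Csn2, the milk protein beta-casein, 84.3-fold. Ang4, an antimicrobial protein of Paneth cells, was 83.2-fold and Saa1, an acute-phase protein of liver, 78.8-fold higher. Of 15 Aire-dependent tissue antigens, 13 were higher and 0 lower (mean 3.72; camera adjusted p = 6.07e-09, and 0.0242 with an estimated correlation). Examples were Mucl2 (5.81 ± 0.12), Csn1s2a (5.22 ± 0.13) and Reg3g (5.03 ± 0.25). Of 14 other tissue antigens, 12 were higher and 0 lower (mean 2.44; adjusted p = 6.07e-09, and 0.0122 with an estimated correlation). These included the testis lipid-binding protein Fabp9 at 4.90 ± 0.16. Of 11 mTEChi markers, 9 were higher and 0 lower (mean 2.36; adjusted p = 5.69e-06), with Fezf2 at 5.48 ± 0.17 and Aire at 4.75 ± 0.12, and adjusted p = 0.0612 with an estimated correlation. With quantile normalization, 1770 genes were higher and 1361 lower, against 2015 and 770 with the deposited values.

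The medullary populations were then compared with each other, ages weighted equally, and 2845 genes differed at least 2-fold, 1713 higher in mTEChi and 1132 higher in mTEClo. Higher in mTEChi were the hormone gene Crh (log2 5.35 ± 0.28 SE, n = 6 against 6, adjusted p = 2.49e-14), Mucl2 (4.99 ± 0.15), Hbb-y (4.89 ± 0.18) and Saa1 (4.86 ± 0.24). Lower were the scramblase gene Plscr2 (−4.36 ± 0.16, adjusted p = 4.15e-17), the activin antagonist Fst (−4.24 ± 0.25) and Slitrk4 (−3.96 ± 0.12). Aire-dependent antigens were higher in mTEChi for 11 of 15 and lower for 0 (mean 2.70; camera adjusted p = 2.84e-07), while the call was lost with adjusted p = 0.0779 with an estimated correlation. Mitosis genes were higher for 22 of 31 and lower for 0 (mean 1.12; adjusted p = 1.82e-09), such as Bub1 (1.76 ± 0.19), with adjusted p = 0.274 with an estimated correlation. Interferon-induced genes were lower in mTEChi for 11 of 21 and higher for 0 (mean −1.12; adjusted p = 8.37e-07), with Ifit3 at −2.77 ± 0.15, and adjusted p = 0.161 with an estimated correlation.

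Cortical against medullary epithelium gave 1978 genes at least 2-fold apart, 783 higher in cTEC and 1195 higher in the mean of both mTEC populations. Scn1a (log2 4.69 ± 0.12 SE, n = 6 against 12, adjusted p = 2.45e-19), the protease gene Prss23 (4.66 ± 0.25) and Psmb11 (4.49 ± 0.19) were highest in cTEC. Insm1, a transcription factor of neuroendocrine cells (−5.07 ± 0.28, adjusted p = 1.2e-13), the desmosomal cadherin Dsg1a (−4.58 ± 0.19) and Crp (−4.54 ± 0.19) were lowest. Markers of cTEC were higher for 12 of 14 and lower for 0 (mean 2.11; camera adjusted p = 6.61e-10, and 0.0261 with an estimated correlation). Aire-dependent antigens were lower for 11 of 15 and higher for 0 (mean −2.11; adjusted p = 7.03e-08, and 0.0409 with an estimated correlation). Thymocyte transcripts differed too: 11 of 15 markers were higher in the cTEC arrays and 0 lower (mean 1.73; adjusted p = 2.89e-07), with Rag1 at 3.42 ± 0.47 and Dntt at 2.67 ± 0.32. That call was lost, adjusted p = 0.317 with an estimated correlation.

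In Sirpa− DC, 899 genes were at least 2-fold higher than in the other 5 populations and 1879 lower. Gcsam, a signalling adaptor known from germinal centres, was 90.4-fold higher (SE 0.11 on the log2 scale, n = 6 against 30, adjusted p = 1.74e-23). Xcr1, the chemokine receptor of cross-presenting DC, was 37.5-fold (5.23 ± 0.11, adjusted p = 7.12e-22), the fatty acid receptor Ffar4 32.8-fold and Cltrn 29.6-fold higher. Of 10 markers of this lineage (cDC1), 10 were higher (mean 3.33; camera adjusted p = 8.06e-10, and 0.00255 with an estimated correlation). These included Itgae (4.62 ± 0.15), Wdfy4 (4.26 ± 0.17), needed for cross-presentation, and the transcription factor Batf3 (4.02 ± 0.10). Mitosis genes were higher for 17 of 31 and lower for 0 (mean 1.08; adjusted p = 1.62e-11), such as Aurkb (1.81 ± 0.17), with adjusted p = 0.176 with an estimated correlation. With array medians made equal, 1255 genes were higher and 1493 lower.

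In Sirpa+ DC, 971 genes were at least 2-fold higher and 1476 lower. Clec4n, the fungal receptor Dectin-2, was 63.0-fold higher (log2 5.98 ± 0.31 SE, n = 6 against 30, adjusted p = 1.05e-14), the complement component C1qa 44.0-fold, Klrd1 43.7-fold, Clec4a3 41.5-fold and the lectin Mgl2 39.5-fold. Of 11 markers of this lineage (cDC2), 11 were higher (mean 3.18; camera adjusted p = 1.23e-10, and 0.00618 with an estimated correlation). Examples were Clec10a (4.35 ± 0.18) and the fractalkine receptor Cx3cr1 (4.22 ± 0.13). Of 27 inflammatory mediators, 17 were higher and 2 lower (mean 1.34; adjusted p = 1.11e-07, and 0.0433 with an estimated correlation). Among them were the chemokine Ccl3 at 4.15 ± 0.17 and the cytokine Il1b at 3.58 ± 0.16. Markers of macrophages were higher for 10 of 11 (mean 3.25; adjusted p = 1.99e-08), such as C1qc (5.25 ± 0.32) and Cd68 (4.48 ± 0.13), with adjusted p = 0.052 with an estimated correlation.

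Between the DC populations, 779 genes differed at least 2-fold, 561 higher in Sirpa+ DC and 218 higher in Sirpa− DC. Clec4a3 (log2 4.12 ± 0.39 SE, n = 6 against 6, adjusted p = 1.12e-08), the chemokine receptor Ccr1 (4.08 ± 0.17), the matrix protease Mmp2 (4.05 ± 0.32) and the chemokine Ccl12 (3.95 ± 0.31) were higher in Sirpa+ DC. Gcsam (−5.25 ± 0.14, adjusted p = 1.35e-18), Cltrn (−4.81 ± 0.16), Xcr1 (−4.58 ± 0.14) and Notch4 (−4.05 ± 0.13) were lower. Of 21 interferon-induced genes, 9 were higher in Sirpa+ DC and 0 lower (mean 1.11; camera adjusted p = 1.49e-12, and 0.0403 with an estimated correlation). These included Oasl2 at 3.36 ± 0.16 and Ifit3 at 3.35 ± 0.15. Of 27 inflammatory mediators, 10 were higher and 1 lower (mean 0.81; adjusted p = 2.38e-07, and 0.0403 with an estimated correlation). Examples were the neutrophil chemokine Cxcl2 (2.80 ± 0.43) and Ptgs2, the inducible cyclooxygenase (2.55 ± 0.29).

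In fibroblasts, 1214 genes were at least 2-fold higher than in the other 5 populations and 1447 lower. Pdgfrb, the receptor for PDGF-BB, was 94.1-fold higher (log2 6.56 ± 0.22 SE, n = 6 against 30, adjusted p = 5.54e-18). The matrix protein Postn was 90.8-fold, Sparcl1 68.9-fold, the transporter Abca8a 66.4-fold and the collagen I chain Col1a2 66.4-fold higher. All 12 fibroblast markers were higher (camera adjusted p = 3.34e-11, and 0.0375 with an estimated correlation), as were 25 of 35 matrix genes with 0 lower (mean 1.92; adjusted p = 6.14e-11), such as Col6a3 (5.27 ± 0.20) and the proteoglycan Bgn (4.26 ± 0.23), though adjusted p = 0.148 with an estimated correlation. Markers of other cell types were high in the same arrays. Of 15 thymocyte markers, 15 were higher (mean 3.50; adjusted p = 1.78e-11), including Dntt (4.65 ± 0.29), Rag1 (4.47 ± 0.42) and the CD3 chain Cd3g (4.34 ± 0.25), with adjusted p = 0.0624 with an estimated correlation. Of 10 mural cell markers, 10 were higher (mean 2.62; adjusted p = 3.32e-08, and 0.0345 with an estimated correlation). Among them were the channel subunits Kcnj8 (5.24 ± 0.10) and Abcc9 (4.05 ± 0.14).

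The next comparisons asked what changed with age within each population, starting with cTEC, where genes of cell division fell. From 1 to 3 months, 26 of 31 mitosis genes fell and 0 rose, or 31 when adjusted over the list alone (mean log2 −1.81; camera adjusted p = 1.66e-41, and 0.0224 with an estimated correlation). Cenpa fell by 2.84 ± 0.35 (SE, n = 2 arrays per age), the spindle protein Nusap1 by 2.75 ± 0.31 and Bub1 by 2.58 ± 0.33. Of 33 E2F targets and replication genes, 18 fell and 1 rose, or 28 and 1 adjusted over the list alone (mean −1.01; adjusted p = 1e-19), led by Rrm2 (−2.52 ± 0.28), which supplies deoxynucleotides, with adjusted p = 0.0543 with an estimated correlation. Markers of cTEC fell for 4 of 14, or 6 adjusted over the list alone (mean −0.88; adjusted p = 2.57e-05), namely Prss16 (−1.41 ± 0.28), Psmb11 (−1.30 ± 0.39), Ccl25 (−1.19 ± 0.33) and the Notch ligand Dll4 (−0.95 ± 0.21). That call was lost, adjusted p = 0.209 with an estimated correlation. The largest rise was in Prg4, a lubricating proteoglycan (3.22 ± 0.32, adjusted p = 3.17e-06), followed by an immunoglobulin kappa segment, Igkv15-103 (3.01 ± 0.78, adjusted p = 0.0241), and the largest falls in the hormone gene Iapp (−3.37 ± 0.60, adjusted p = 0.00128) and S100a8 (−3.09 ± 0.72, adjusted p = 0.0113). The thymocyte markers fell in the same arrays, for 6 of 15 or 12 adjusted over the list alone (mean −1.42; adjusted p = 2.06e-07, and 0.421 with an estimated correlation). The 3′ minus 5′ probe difference of Gapdh and Actb went from log2 2.53 ± 0.14 (SD) to 1.99 ± 0.068. In all, 783 genes changed, 221 up and 562 down, or 262 up and 369 down with quantile normalization and 284 up and 380 down with equal medians. With the thymocyte mean as a covariate the count was 117, 18 up and 99 down, and with the 3′ minus 5′ difference 409, 128 up and 281 down. Without replicate 1 of cTEC at 1 month the count was 138, and without replicate 1 or 2 at 3 months it was 234 or 514.

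From 1 to 6 months in cTEC, mitosis genes were again lower, 25 of 31 with 0 higher, or 29 adjusted over the list alone (mean −1.27; camera adjusted p = 5.25e-25, and 0.177 with an estimated correlation). The anaphase activator Cdc20 fell by 2.24 ± 0.43, Aurkb by 1.94 ± 0.37, Cenpf by 1.70 ± 0.44 and the proliferation antigen Mki67 by 1.66 ± 0.26 (SE, n = 2 arrays per age). Of the E2F targets, 12 of 33 fell and 0 rose, or 17 adjusted over the list alone (mean −0.74; adjusted p = 2.38e-12, and 0.264 with an estimated correlation), led by Uhrf1 (−2.01 ± 0.28), which maintains DNA methylation, and Rrm2 (−1.81 ± 0.28). Matrix genes fell for 8 of 35 and rose for 0, or 9 adjusted over the list alone (mean −0.65; adjusted p = 0.000665, and 0.727 with an estimated correlation). These included Ogn (−2.43 ± 0.52) and the basement membrane gene Nid1 (−2.41 ± 0.41). Igkv15-103 rose by 4.59 ± 0.78 (adjusted p = 0.00062), Otog, a protein of the inner ear matrix, by 4.48 ± 0.29 (adjusted p = 9.03e-10), and the light chain segment Iglv1 by 4.44 ± 1.23 (adjusted p = 0.0283). The peptidase Mme (CD10) fell by 3.62 ± 0.56 (adjusted p = 0.000228), S100a8 by 3.47 ± 0.72 (adjusted p = 0.00379) and the acute-phase gene Saa3 by 3.27 ± 0.48 (adjusted p = 0.000149). The 3′ minus 5′ difference was 2.00 ± 0.058 (SD) at 6 months, and the mean of the thymocyte markers was 8.06, from 8.49 at 1 month. In all, 935 genes changed, 393 up and 542 down, or 561 up and 468 down with equal medians and 317 up and 250 down with the 3′ minus 5′ difference as a covariate. Leaving out replicate 1 at 1 month gave 299 genes and 10 of the mitosis genes, leaving out replicate 1 at 6 months 546 and 14, and leaving out replicate 2 at 6 months 437 genes.

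In mTEClo, too, genes of division were among those that fell with age. From 1 to 6 months, 27 of 31 mitosis genes fell and 0 rose, or 30 adjusted over the list alone (mean −1.61; camera adjusted p = 4.18e-34, and 0.0534 with an estimated correlation). Cdc20 (−2.79 ± 0.43), Cenpa (−2.56 ± 0.35) and Bub1 (−2.45 ± 0.33) fell most (SE, n = 2 arrays per age). Of the E2F targets, 20 of 33 fell and 0 rose, or 27 adjusted over the list alone (mean −0.94; adjusted p = 2.18e-18, and 0.0708 with an estimated correlation). Largest were Rrm2 (−2.33 ± 0.28) and the cyclin Ccne2 (−1.92 ± 0.33). Of 26 regulators of the Rb and E2F pathway, 6 fell and 0 rose, or 8 adjusted over the list alone (mean −0.46; adjusted p = 0.00469, and 0.477 with an estimated correlation). Among them were the repressors E2f7 (−1.94 ± 0.32) and E2f8 (−1.56 ± 0.18). Markers of mTEChi fell for 3 of 11 and rose for 0, also when adjusted over the list alone (mean −0.80; adjusted p = 0.00451, and 0.477 with an estimated correlation). These were Cdx1 (−2.45 ± 0.38), Aire (−2.08 ± 0.27) and Cd40 (−1.17 ± 0.29). Aire-dependent antigens fell for 3 of 15 and rose for 0, or 7 adjusted over the list alone (mean −0.96; adjusted p = 0.000158, and 0.296 with an estimated correlation). An example was the trefoil factor Tff3 (−2.38 ± 0.37). The largest falls were in Hbb-y (−4.90 ± 0.32, adjusted p = 6.12e-10), Saa1 (−3.47 ± 0.41, adjusted p = 7.76e-06) and Calcb (−3.46 ± 0.68, adjusted p = 0.00201), and the largest rise in the calcium channel Ryr3 (3.86 ± 0.44, adjusted p = 5.26e-06). The 3′ minus 5′ difference went from log2 2.67 to 1.91 and the mean of the thymocyte markers from 6.64 to 6.01. In all, 930 genes changed, 369 up and 561 down, or 525 up and 553 down with quantile normalization and 187 up and 195 down with the 3′ minus 5′ difference as a covariate. Leaving out replicate 1 or 2 at 6 months gave 348 or 467 genes, and leaving out replicate 1 or 2 at 1 month 402 or 468.

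Between 1 and 3 months in mTEClo, mitosis genes fell for 6 of 31 and rose for 0, or 21 adjusted over the list alone (mean −0.80; camera adjusted p = 1.1e-17, and 0.267 with an estimated correlation). These included Nusap1 (−1.50 ± 0.31; SE, n = 2 arrays per age). Markers of mTEChi fell for 3 of 11 and rose for 0, or 5 adjusted over the list alone (mean −0.73; adjusted p = 3.55e-05, and 0.267 with an estimated correlation). These included Aire at −1.72 ± 0.27 and Fezf2 at −1.66 ± 0.37. Prg4 rose by 3.82 ± 0.32 (adjusted p = 1.07e-07) and the iron-binding protein Lcn2 by 2.56 ± 0.45 (adjusted p = 0.002). The muscle genes Myh1 (−3.25 ± 0.74, adjusted p = 0.0183) and Ttn (−2.55 ± 0.49, adjusted p = 0.00443) and the globin Hbb-y (−2.67 ± 0.32, adjusted p = 2.32e-05) fell. The thymocyte markers fell in the same arrays, for 1 of 15 with 0 rising, or 4 adjusted over the list alone (mean −0.95; adjusted p = 8.58e-05, and 0.535 with an estimated correlation), and the 3′ minus 5′ difference averaged 2.48 with an SD of 0.826 at 3 months. In all, 257 genes changed, 90 up and 167 down, or 161 with the thymocyte mean as a covariate (56 up and 105 down), and without replicate 2 at 3 months, replicate 2 at 1 month or replicate 1 at 1 month the count was 63, 71 or 169.

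In mTEChi, no change of the mitosis genes as a group was detected from 1 to 6 months. Of 31 mitosis genes 1 fell, Plk1 (log2 −0.99 ± 0.25 SE, n = 2 arrays per age), and 0 rose, also when adjusted over the list alone (mean 0.19; camera adjusted p = 0.586). Genes of ribosome production rose for 6 of 22 and fell for 0, or 8 adjusted over the list alone (mean 0.41; adjusted p = 0.00413, and 0.905 with an estimated correlation), such as the nucleolar proteins Nolc1 (1.72 ± 0.28) and Npm1 (1.02 ± 0.17). Markers of mTEChi rose for 4 of 11 and fell for 0, or 5 adjusted over the list alone (mean 0.76; adjusted p = 0.00413, and 0.905 with an estimated correlation), with the chemokine Ccl17 at 1.57 ± 0.37, Fezf2 at 1.33 ± 0.37 and Aire at 0.84 ± 0.27. Of 15 Aire-dependent antigens 1 rose, Csn3 (0.84 ± 0.27), or 3 adjusted over the list alone, and 0 fell (mean 0.51; adjusted p = 0.0942, and 0.905 with an estimated correlation). Single genes included the antiviral kinase Eif2ak2 (2.53 ± 0.21, adjusted p = 1.37e-07), the immunoglobulin heavy chain Ighm (3.42 ± 0.99, adjusted p = 0.0297, the same sign in 6 of 9 probe sets), the crystallin Cryl1 (−4.14 ± 0.86, adjusted p = 0.00364) and the calcium-binding S100g (−2.87 ± 0.25, adjusted p = 1.37e-07). In all, 1379 genes changed, 895 up and 484 down, or 1019 up and 956 down with quantile normalization. Leaving out replicate 2 or 1 at 1 month gave 603 or 666 genes, leaving out replicate 2 or 1 at 6 months gave 735 or 2732, and a fit of these 4 arrays alone gave 14. From 1 to 3 months limma called 0 genes, with 385 at an unadjusted p under 0.05, and 1 to 6 genes were called when replicate 2 at 3 months (1), either Sirpa+ DC array at 3 months (2), replicate 2 at 1 month (4) or either mTEChi array at 6 months (6) was left out.

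The study is known to report a lower E2F program with age in thymic epithelium, and the change of division genes was tested over the 3 epithelial populations and against the DC. In the epithelial mean from 1 to 6 months, 18 of 33 E2F targets fell and 0 rose, or 22 adjusted over the list alone (mean log2 −0.52; camera adjusted p = 2.42e-10, and 0.43 with an estimated correlation). Examples were Rrm2 at −1.36 ± 0.16 and the replication licensing factor Cdc6 at −1.32 ± 0.16 (SE, n = 6 arrays per age). In mTEChi the mean of the E2F list did not fall, at log2 8.325 at 1 month and 8.453 at 6 months, so cTEC and mTEClo carried the fall. Of 31 mitosis genes, 27 fell and 0 rose, or 29 adjusted over the list alone (mean −0.90; adjusted p = 4.68e-21, and 0.316 with an estimated correlation). Among them were Aurkb (−1.58 ± 0.22) and Plk1 (−1.33 ± 0.15). The difference between epithelial and DC changes was tested directly. Mitosis genes fell more in epithelium for 19 of 31, or 29 adjusted over the list alone (mean difference −1.02; adjusted p = 4.29e-30), such as Ube2c (−1.52 ± 0.31), but with adjusted p = 0.0888 with an estimated correlation. E2F targets fell more for 3 of 33, or 11 adjusted over the list alone (mean difference −0.52; adjusted p = 3.16e-12, and 0.136 with an estimated correlation). Over all genes, 277 differed in their change, 130 in favour of epithelium (171 with equal medians), such as the cadherin Cdh2 (2.31 ± 0.35, adjusted p = 0.000721), and 147 in favour of DC (150 with equal medians), led by the scavenger receptor Cd163 (−3.67 ± 0.67, adjusted p = 0.00336). That count was 836 without replicate 1 of mTEChi at 6 months and 184 without replicate 1 of cTEC at 1 month. It was 154, 162 and 169 without replicates 2 and 1 of Sirpa− DC at 6 months and replicate 1 at 1 month, and 144, 182 and 156 without replicates 1 and 2 of Sirpa+ DC at 6 months and replicate 1 at 1 month.

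**Figure D2:**
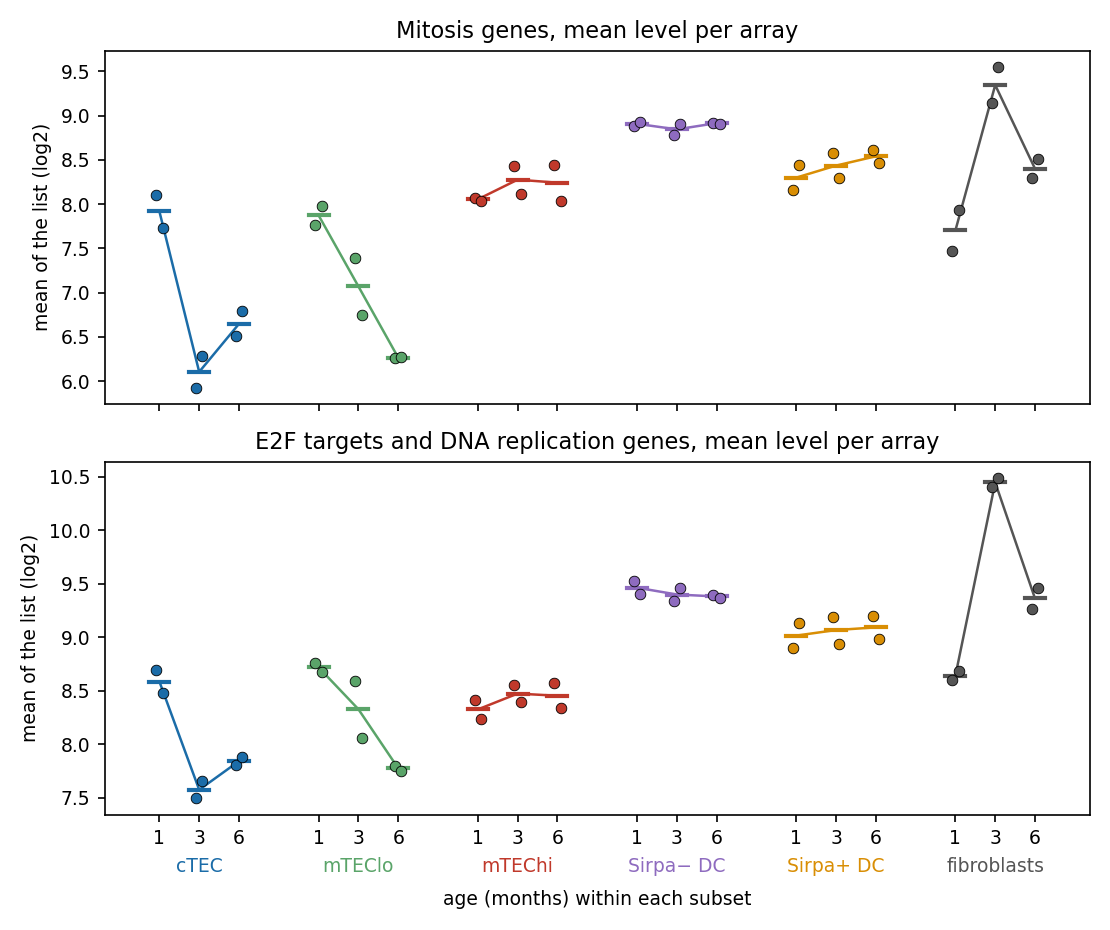
The mean log2 signal of the mitosis genes and of the E2F targets and replication genes in each array, by population and age in months; points are arrays and bars are means of 2. In mTEClo the mitosis mean is 7.87 at 1 month and 6.27 at 6 months, in mTEChi 8.05 and 8.24, and in Sirpa− DC 8.91 and 8.92.

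The study is known to report inflammatory genes in older DC, and 3 of 27 inflammatory mediators rose from 1 to 6 months in each DC population, calls on the list that were lost with an estimated correlation. In Sirpa− DC, Cd163 rose by log2 5.22 ± 0.73 (SE, n = 2 arrays per age, adjusted p = 0.00035), the adhesion receptor Adgre4 by 3.60 ± 0.43 (adjusted p = 6.47e-05) and Adamdec1 by 3.47 ± 0.79 (adjusted p = 0.0332), while Cdh2 fell by 3.10 ± 0.38 (adjusted p = 7.49e-05). Inflammatory mediators rose for 3 of 27 and fell for 0, or 5 adjusted over the list alone (mean 0.48; camera adjusted p = 9.26e-05, and 0.14 with an estimated correlation). These were Ccl3 (2.12 ± 0.37), the endotoxin receptor Cd14 (1.55 ± 0.31) and Ccl4 (1.48 ± 0.25). Macrophage markers rose in the same arrays for 2 of 11 and fell for 0, or 7 adjusted over the list alone (mean 1.65; adjusted p = 4.36e-08, and 0.14 with an estimated correlation). The 2 were Cd163 and the iron exporter Slc40a1 (3.20 ± 0.75). The mean of the macrophage markers was log2 7.68 and 6.62 in the arrays at 1 month and 8.72 and 8.88 at 6 months, and its rise was 1.12 without replicate 2 at 1 month. Of the markers, 1 was called without that array or either array at 6 months, and 4 without either array at 3 months. In Sirpa+ DC their mean change was −0.14 (adjusted p = 0.435), and the difference between the DC populations was not tested. In Sirpa+ DC, the prostaglandin receptor Ptger3 rose by 2.25 ± 0.28 (adjusted p = 7.79e-05) and Ptgs2 by 2.13 ± 0.51 (adjusted p = 0.0235), while Cdh2 fell by 3.18 ± 0.38 (adjusted p = 7.67e-05). Inflammatory mediators rose for 3 of 27 and fell for 1, or 5 and 2 adjusted over the list alone (mean 0.28; adjusted p = 0.0314, and 0.719 with an estimated correlation). Examples were Ccl3 at 1.58 ± 0.37 and the IL-1 antagonist Il1rn at −1.54 ± 0.27. In the mean of both, 6 of 27 rose and 2 fell, the same when adjusted over the list alone (mean 0.38; adjusted p = 0.00169, and 0.299 with an estimated correlation). Among them were Ccl3 at 1.85 ± 0.26 and Ptgs2 at 1.58 ± 0.36 (n = 4 per age). Genes known to respond to tissue dissociation rose with them, 9 of 20 with 0 falling, or 14 adjusted over the list alone (mean 0.76; adjusted p = 2.76e-10, and 0.299 with an estimated correlation). These included Junb (adjusted p = 0.000204) and Nr4a1 (adjusted p = 0.000469). Thymocyte markers fell for 4 of 15, or 6 adjusted over the list alone (mean −0.70; adjusted p = 0.000114, and 0.388 with an estimated correlation), and the 3′ minus 5′ difference went from 1.80 to 1.42 in Sirpa− and from 1.78 to 1.47 in Sirpa+ DC. Of the E2F targets 1 rose and 1 fell, also when adjusted over the list alone (adjusted p = 0.953, with the mean at −0.002 and the median at 0.002).

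In numbers, 131 genes changed from 1 to 6 months in Sirpa− DC, 78 up and 53 down, and 299 in Sirpa+ DC, 195 up and 104 down. These counts were 276 (216 up and 60 down) and 737 (553 up and 184 down) with the mean of probe sets, 1520 and 1703 with array weights, and 1230 and 1267 with only the groups compared. With the thymocyte mean as a covariate they were 217 and 517, and in Sirpa− DC 71 with the 3′ minus 5′ difference. From 1 to 3 months, 48 changed in Sirpa+ DC, 20 up and 28 down, and 5 in Sirpa− DC, 2 up and 3 down (5 and 4 with quantile normalization, 5 and 2 with equal medians). As a list, interferon-induced genes rose for 2 of 21 only when adjusted over the list alone, in Sirpa− DC (mean log2 0.014; camera adjusted p = 0.994) and in Sirpa+ DC (mean 0.186; adjusted p = 0.00941, and 0.776 with an estimated correlation). The interferon-inducible GTPase Iigp1 rose by log2 2.58 ± 0.29 in Sirpa− DC (SE, n = 2 arrays per age, adjusted p = 5.02e-05) and by 2.27 ± 0.29 in Sirpa+ DC (adjusted p = 9.15e-05), where Ifitm1 rose by 3.36 ± 0.42 (adjusted p = 6.86e-05) and Gbp2b by 3.02 ± 0.34 (adjusted p = 5.01e-05). Cdh2 fell by 2.64 ± 0.38 in Sirpa− DC (adjusted p = 0.00167) and by 3.30 ± 0.38 in Sirpa+ DC (adjusted p = 5.01e-05), and Zfp180 and the lectin receptor Klrb1b fell by 1.45 and 1.20 in Sirpa− DC. The fifth gene there, Gm4951, rose by 2.40 (adjusted p = 0.000352) and was named after its values were seen. At 6 months, the count in Sirpa− DC was 16 and 29 without replicates 2 and 1 of that age, 24 and 75 without replicates 1 and 2 at 1 month, and 212 without either mTEChi array at 6 months. In Sirpa+ DC it was 23 and 92 without replicates 1 and 2 at 6 months, 37 and 164 without replicates 1 and 2 at 1 month, and 601 without either mTEChi array at 6 months. At 3 months, the count in Sirpa+ DC was 20 and 30 without replicates 1 and 2 at 1 month. In Sirpa− DC it was 3 and 22 without replicates 1 and 2 at 1 month, 14 without replicate 1 at 3 months, 11 without either cTEC array at 1 month and 12 without either fibroblast array at 6 months.

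In fibroblasts, matrix genes and fibroblast markers fell with age while thymocyte markers rose. From 1 to 6 months, 34 of 35 matrix genes fell and 0 rose, or 35 adjusted over the list alone (mean log2 −2.64; camera adjusted p = 1.48e-20, and 0.407 with an estimated correlation), with the collagen Col14a1 at −4.25 ± 0.38, Ogn at −3.82 ± 0.52 and Mmp2 at −3.79 ± 0.56 (SE, n = 2 arrays per age). Fibroblast markers fell for 10 of 12 and rose for 0, also when adjusted over the list alone (mean −2.05; adjusted p = 0.00014, and 0.49 with an estimated correlation), such as the collagen I chain Col1a1 (−3.48 ± 0.43) and the surface protease Fap (−3.19 ± 0.50). Growth factors and morphogens fell for 15 of 31 and rose for 0, or 18 adjusted over the list alone (mean −1.09; adjusted p = 6.29e-05, and 0.407 with an estimated correlation), such as Aldh1a1 (−3.78 ± 0.37), which makes retinoic acid, and Tgfb2 (−2.92 ± 0.47). Thymocyte markers rose for 11 of 15 and fell for 0, also when adjusted over the list alone (mean 1.39; adjusted p = 8.05e-06, and 0.49 with an estimated correlation), such as the pre-T cell receptor chain Ptcra (2.19 ± 0.29), and the gamma chain segment Trgv4 rose by 3.88 ± 0.37 (adjusted p = 1.4e-07). Among single genes, parathyroid hormone, Pth, fell by 6.57 ± 1.47 (adjusted p = 0.00127) and Chga, of neuroendocrine cells, by 4.23 ± 0.83 (adjusted p = 0.000408). The mean of the thymocyte markers was log2 9.64 ± 1.08 (SD) at 1 month, 10.38 at 3 months and 11.04 ± 0.254 at 6 months, and the 3′ minus 5′ difference went from 2.76 ± 0.551 to 2.11 and 1.79. In all, 5251 genes changed, 2296 up and 2955 down, or 2696 up and 2360 down with quantile normalization and 3329 up and 2265 down with equal medians, under which the median change of all genes moved by 0.17. With the thymocyte mean as a covariate the count was 1596, 534 up and 1062 down, and with the 3′ minus 5′ difference 2697, 1353 up and 1344 down. Without replicate 2 at 6 months the count was 2147, with 4 fibroblast markers, 5 thymocyte markers and 29 matrix genes called, and list means of −0.943, 1.215 and −1.736. Without replicate 1 at 1 month it was 2308, with 7, 2 and 32 called and means of −1.972, 0.63 and −2.353. The fibroblast marker mean was −3.159 without replicate 1 at 6 months, and the thymocyte mean 2.158 without replicate 2 at 1 month. A limma fit of these 4 arrays alone called 0 genes, with 4346 at an unadjusted p under 0.05.

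Between 1 and 3 months in fibroblasts, E2F targets rose for 32 of 33 and fell for 0, also when adjusted over the list alone (mean log2 1.81; camera adjusted p = 2.5e-37, and 0.00567 with an estimated correlation). The cyclin Ccne2 rose by 3.02 ± 0.33, Uhrf1 by 2.53 ± 0.28 and the repair gene Brca1 by 2.43 ± 0.27 (SE, n = 2 arrays per age). Mitosis genes rose for 29 of 31 and fell for 0, also when adjusted over the list alone (mean 1.64; adjusted p = 1.88e-26, and 0.0754 with an estimated correlation). These included Ect2 (2.64 ± 0.32). Matrix genes fell for 28 of 35 and rose for 0, or 30 adjusted over the list alone (mean −1.49; adjusted p = 1.4e-14, and 0.264 with an estimated correlation). Among them were Col15a1 (−2.53 ± 0.60) and Col5a1 (−2.34 ± 0.49). The cohesin factor Esco2 rose by 3.72 ± 0.45 (adjusted p = 4.17e-06), and the carbonic anhydrase Car2 fell by 3.48 ± 0.68 (adjusted p = 0.000854). Among the largest rises were also the gamma chain segments Trgv1 (3.54 ± 0.37, adjusted p = 1.09e-06) and Trgv4 (3.42 ± 0.37, adjusted p = 1.28e-06). Thymocyte markers rose for 4 of 15 and fell for 0, also when adjusted over the list alone (mean 0.73; adjusted p = 0.00851, and 0.739 with an estimated correlation). These included Ptcra at 2.65 ± 0.29. Whether the rise of the E2F and mitosis genes lay in fibroblasts or in thymocyte RNA of these arrays was not tested. In all, 2962 genes changed, 1457 up and 1505 down, or 1631 up and 1523 down with quantile normalization. It was 1864, 1191 up and 673 down, with the 3′ minus 5′ difference as a covariate and 1894, 1025 up and 869 down, with the thymocyte mean, and without replicate 2 at 3 months or replicate 1 at 1 month the count was 1060 or 1078.

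**Figure D3:**
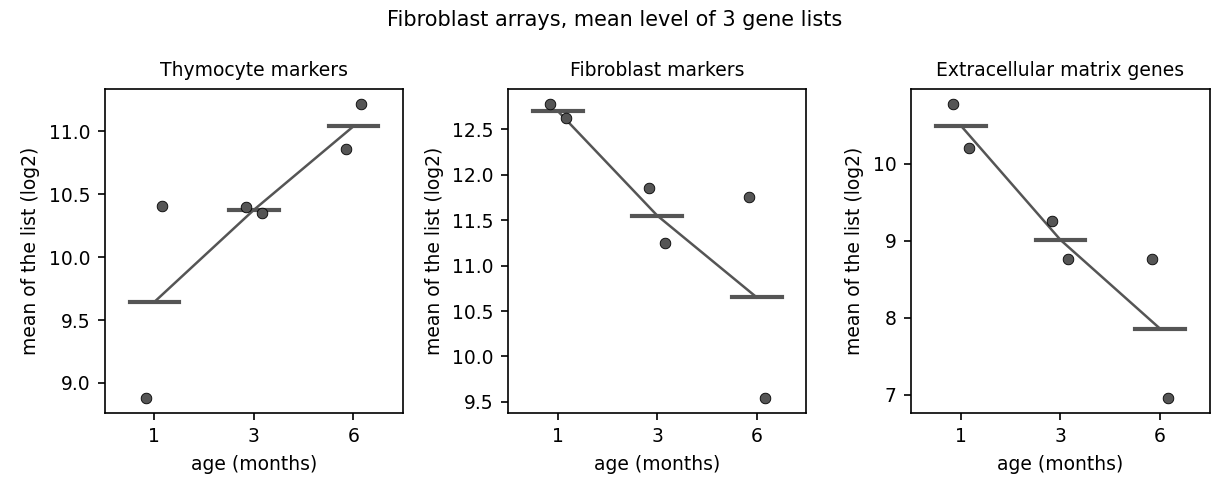
The mean log2 signal of the thymocyte markers, the fibroblast markers and the extracellular matrix genes in the 6 fibroblast arrays, by age in months, each panel with its own axis; points are arrays and bars are means of 2. The fibroblast marker mean is 12.70 at 1 month and 10.65 at 6 months, where the arrays are at 11.76 and 9.54.

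The last comparisons asked which genes changed with age across the 6 populations and where the changes differed. From 1 to 6 months, in the mean of the 6, matrix genes fell for 25 of 35 and rose for 0, or 28 adjusted over the list alone (mean log2 −0.64; camera adjusted p = 3.54e-08, and 0.748 with an estimated correlation). Examples were Nid1 (−1.29 ± 0.17) and Ogn (−1.21 ± 0.21; SE, n = 12 arrays per age). Without the fibroblast arrays, a fit chosen after the data were seen, 14 of 35 fell and 0 rose. Their mean was then −0.239 (camera adjusted p = 0.00648, and 0.561 with an estimated correlation). Dissociation and immediate early genes rose for 11 of 20 and fell for 0, or 12 adjusted over the list alone (mean 0.34; adjusted p = 0.000628, and 0.748 with an estimated correlation). These included Ier2 (0.79 ± 0.13). Moving the same way in all 6 populations, Ighm rose by 1.59 ± 0.40 (adjusted p = 0.00361) and the small GTPase Rap2b by 1.58 ± 0.11 (adjusted p = 1.88e-10, the same sign in 2 of 3 probe sets). Btbd3 fell by 1.73 ± 0.19 (adjusted p = 4.96e-07, the same sign in 1 of 2 probe sets), the ephrin receptor Epha3 by 1.71 ± 0.25 (adjusted p = 1.53e-05) and Saa3 by 1.58 ± 0.20 (adjusted p = 2.25e-06). Of the E2F targets, 12 of 33 fell and 5 rose, or 13 and 5 adjusted over the list alone (mean −0.14; adjusted p = 0.239). In the 5 populations other than fibroblasts, chosen after the data were seen, 17 fell and 0 rose (mean −0.31; adjusted p = 5.61e-05, and 0.58 with an estimated correlation). In all, 5302 genes changed, 2160 up and 3142 down, or 2739 up and 2359 down with equal medians. This takes the 12 arrays of an age as independent. With arrays averaged per age and replicate number 2692 were called, 1185 up and 1507 down. The count was 1575, 1018 up and 557 down, with the 3′ minus 5′ difference as a covariate. That difference was lower at 6 than at 1 month in each population, by group means.

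From 1 to 3 months in the mean of the 6 populations, thymocyte markers fell for 10 of 15 and rose for 0, or 11 adjusted over the list alone (mean log2 −0.58; camera adjusted p = 2.56e-05, and 0.615 with an estimated correlation). These included Rag1 (−1.46 ± 0.39) and Cd8b1 (−1.02 ± 0.21; SE, n = 12 arrays per age). Of 21 interferon-induced genes, 4 rose and 0 fell, or 5 adjusted over the list alone (mean 0.15; adjusted p = 0.00169, and 0.615 with an estimated correlation). Examples were the GTPases Gbp2 (0.78 ± 0.10) and Igtp (0.56 ± 0.09). The protease inhibitor Slpi rose by 2.26 ± 0.56 (adjusted p = 0.0187) and the antibody joining chain Jchain by 2.16 ± 0.66 (adjusted p = 0.0493), while S100a8 fell by 1.62 ± 0.29 (adjusted p = 0.00249) and Itm2a by 1.19 ± 0.13 (adjusted p = 2.43e-05). From 3 to 6 months, interferon-induced genes fell for 9 of 21 and rose for 0, or 12 and 2 adjusted over the list alone (mean −0.23; adjusted p = 0.0115, and 0.881 with an estimated correlation), such as Gbp3 (−0.90 ± 0.15), and Slpi fell by 1.79 ± 0.56 (adjusted p = 0.0169). Dissociation and immediate early genes rose for 13 of 20 and fell for 0, or 14 adjusted over the list alone (mean 0.53; adjusted p = 8.46e-07, and 0.881 with an estimated correlation), such as Ier2 (1.08 ± 0.13). The zinc finger gene Zfp458 rose by 1.76 ± 0.13 (adjusted p = 3.55e-10), the ligase scaffold Cul5 by 1.75 ± 0.15 (adjusted p = 6.45e-09) and the nuclear RNA Malat1 by 1.66 ± 0.13 (adjusted p = 8.81e-10). In all, 4561 genes changed from 3 to 6 months, 2244 up and 2317 down (2476 up and 2105 down with equal medians), and 919 from 1 to 3 months, 267 up and 652 down, or 506 up and 560 down with quantile normalization and 406 up and 489 down with equal medians. These counts take the 12 arrays of an age as independent. With arrays averaged per age and replicate number, 1887 genes were called from 3 to 6 months, 1065 up and 822 down. The count of 919 was 13 in that fit, and 278 with age and replicate number as a random block. It was 134, 54 up and 80 down, with the 3′ minus 5′ difference as a covariate, and 437 without replicate 2 of fibroblasts at 3 months, 468 and 583 without replicate 2 at 3 months and replicate 1 at 1 month of mTEClo, and 492 and 542 without replicate 2 at 3 months and replicate 1 at 1 month of mTEChi. It was 555 without replicate 2 of cTEC at 3 months and 567 without replicate 1 of Sirpa− DC at 1 month.

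The changes with age differed between the 6 populations for 2278 genes. This count was 947 with the thymocyte mean as a covariate, 1237 without replicate 1 of fibroblasts at 1 month and 4070 without replicate 1 of mTEChi at 6 months. The 2 contrasts below were chosen after the data were seen. Fibroblasts differed from the mean of the other 5 in the change from 1 to 6 months for 3823 genes, 1561 upward and 2262 downward, or 1943 and 1897 with quantile normalization and 2420 and 1873 with equal medians. Matrix genes fell more in fibroblasts for 33 of 35, or 34 adjusted over the list alone (mean difference log2 −2.40; camera adjusted p = 4.55e-21, and 0.247 with an estimated correlation). The mean of cTEC and mTEClo differed from mTEChi for 1113 genes, 265 upward and 848 downward, or 420 and 496 with quantile normalization and 314 and 709 with equal medians. Mitosis genes fell more in cTEC and mTEClo for 25 of 31, or 29 adjusted over the list alone (mean difference −1.63; adjusted p = 1.31e-23, and 0.117 with an estimated correlation). The largest change was in Cdc20 (−3.01 ± 0.53 SE). Markers of mTEChi fell more for 6 of 11, or 8 adjusted over the list alone (adjusted p = 2.07e-06, and 0.117 with an estimated correlation), and Aire-dependent antigens for 6 of 15, or 9 adjusted over the list alone (mean difference −1.11; adjusted p = 0.000553, and 0.351 with an estimated correlation).

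**Figure D4:**
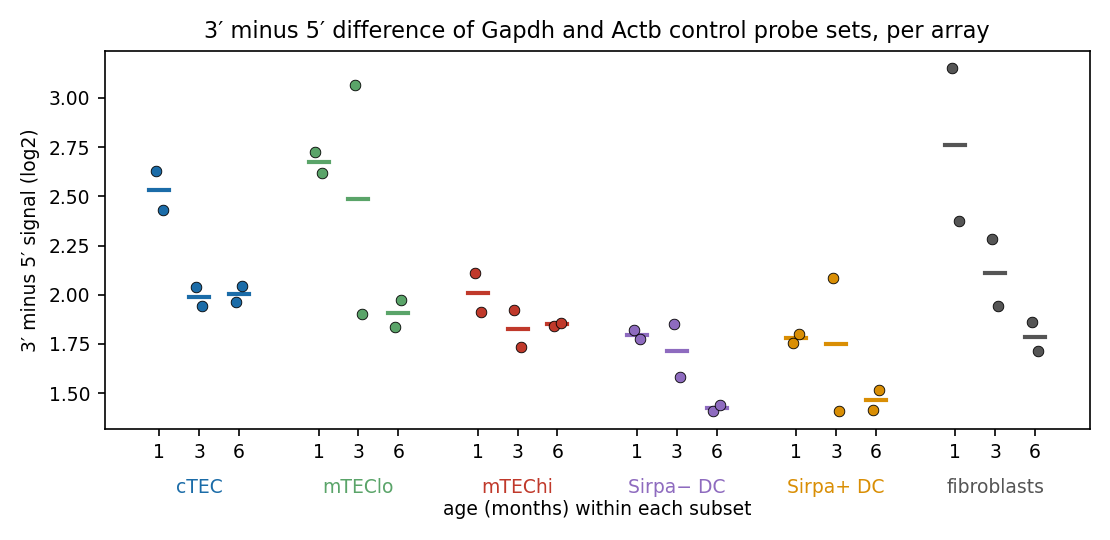
The 3′ minus 5′ probe set difference of Gapdh and Actb (mean, log2) in each of the 36 arrays, by population and age in months; points are arrays and bars are means of 2. In fibroblasts the mean is 2.76 at 1 month and 1.79 at 6 months, and in mTEChi 2.01 and 1.85.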

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

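The 2 contrasts of fibroblasts with the other 5 populations and of cTEC and mTEClo with mTEChi, the fit without fibroblast arrays, the other gene sets and the intervals for the dilution test, and the test for thymocytes in the fibroblast sort were chosen only after the results were seen. Results are given here because the change with age differed between groups by a test of the difference itself. The change from 1 to 6 months differed between epithelial and DC populations for 277 genes, against at most 19 in 99 other splits of the arrays within populations, so 1 of 100 splits gave as many and chance can be excluded. The count was 836 without replicate 1 of mTEChi at 6 months, 184 without replicate 1 of cTEC at 1 month, 154, 162 and 169 without replicates 2 and 1 of Sirpa− DC at 6 months and replicate 1 at 1 month, and 144, 182 and 156 without replicates 1 and 2 of Sirpa+ DC at 6 months and replicate 1 at 1 month. The changes with age differed between the 6 populations for 2278 genes, against at most 991 in the other splits, 1 of 100 giving as many. Of the other splits, 82 called at least 1 gene. The same limits hold for these splits, so chance is not excluded there. This count also moved both ways when single arrays were left out. Fibroblasts differed from the other 5 populations for 3823 genes, and cTEC with mTEClo from mTEChi for 1113 genes. Among the fixed lists, 19 mitosis genes fell more in epithelium than in DC, 25 fell more in cTEC with mTEClo than in mTEChi, and 33 matrix genes fell more in fibroblasts than in the others. With an estimated correlation these list calls were lost, with adjusted p = 0.0888, 0.117 and 0.247.

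Mitosis genes were lower at 6 months in cTEC and mTEClo. Thymocyte RNA and RNA quality were tested as covariates. The mean log2 change in cTEC was −1.27 ± 0.217 (SE) without a covariate, −1.144 ± 0.194 with the thymocyte mean and −1.185 ± 0.239 with the 3′ minus 5′ difference. In mTEClo it was −1.608 ± 0.217, −1.426 ± 0.2 and −1.484 ± 0.26. The slope was 0.291 ± 0.11 for the thymocyte mean and 0.162 ± 0.184 for the 3′ minus 5′ difference. Each is 1 slope for all populations, taken from differences between the 2 arrays of a group. If that slope also holds across ages in cTEC and mTEClo, the values argue against either as the whole cause. Loss of mTEChi cells from the 1-month mTEClo sort would lower mitosis genes by the same share of the mTEChi level as other mTEChi genes. The median share was 0.858 (quartiles 0.706 to 1.006, 15 genes) against 0.079 (0.024 to 0.209) for 370 genes high in mTEChi. These 370 were chosen with every mTEChi array above every mTEClo array, which favours a low share in them. The comparison therefore does not decide it, and loss of mTEChi cells stays open. A lower share of dividing cells with age in cTEC and mTEClo stays open as a hypothesis and was not tested, as does a difference between the mice or sorts of each age, which the labels do not separate from age. Leaving out replicate 1 of cTEC at 1 month left 10 of 31 mitosis genes called in cTEC, and leaving out replicate 1 at 6 months left 14.

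In the fibroblast arrays thymocyte transcripts rose, and fibroblast and matrix genes fell, from 1 to 6 months. Thymocytes in the sort stay open as the origin of the transcripts: all 15 thymocyte markers were higher in the fibroblast arrays than in the other populations, but this count restates the pattern and does not test what brought them there. Dilution by thymocyte RNA alone would lower all fibroblast genes alike, and the spread of their changes over their SE was 2.608 in 26 genes. This is past the bound of 2 written beforehand, but by less than its own spread, since resampling the genes gave a 95% interval from 1.269 to 6.053. Without Abcc9, Kcnj8 and Ptcra, which were on the lists of other cell types, the 23 genes left gave 2.085 (0.96 to 5.114). Of the 26 genes, 4 rose and 21 fell, and some that rose, such as Gfi1 (log2 1.875), were still among the 23. The 26 were chosen as high in arrays that also held thymocyte transcripts. A gene that rose may therefore come from thymocytes and would widen the spread. The 29 genes of the fibroblast and matrix lists gave 1.524 (0.904 to 2.833). With these intervals dilution and a change within fibroblasts cannot be told apart. Without replicate 2 at 6 months 4 fibroblast and 5 thymocyte markers were called, and without replicate 1 at 1 month 7 and 2; no biological explanation was tested, and age stays open.

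In the mean of the 6 populations, 5302 genes changed from 1 to 6 months and 4561 from 3 to 6 months. Fibroblast arrays alone are argued against as the source, since 4161 genes were called without them. A difference in RNA quality or labelling stays open. With the 3′ minus 5′ difference as a covariate 1575 genes were called from 1 to 6 months, 1018 up and 557 down, against 2160 up and 3142 down without it. This met the bound written beforehand for such a cause, but the difference was lower at 6 than at 1 month in each population. A covariate that moves with age lowers the count with or without an effect of RNA quality, so the drop does not decide it. A chance division of the arrays within populations can be excluded if the arrays are independent, with at most 215 and 138 genes in the other splits and 1 of 100 giving as many in each comparison. With arrays averaged per age and replicate number 2692 and 1887 genes were called. However, a shared day of sorting or hybridisation for each age, on which the labels are silent, cannot be separated from age. Age itself stays open and untested as the cause.

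The other splits of the arrays gave the following, each out of 100. The real count was the highest, 1 of 100, for the genes higher in cTEC (1411, highest other 560), mTEClo (1365, 467), mTEChi (2015, 232), Sirpa− DC (899, 405), Sirpa+ DC (971, 35) and fibroblasts (1214, 1152). It was also the highest for mTEChi against mTEClo (2845, 1873) and for Sirpa+ against Sirpa− DC (779, 483). These splits put arrays of different populations into 1 group, which widens the spread of the fit and favours the real labels. For fibroblasts against the others, only 4 of the other splits called any gene. No conclusion on chance is drawn from these ranks. For 3 against 1 month in the mean of the 6 populations (919, 745) the real count was also the highest, 1 of 100. The splits within populations take the arrays as independent, although the 12 arrays of an age may come from 2 mice. The count was 278 with age and replicate number as a random block and 13 with arrays averaged per age and replicate number, so chance is excluded there only if the arrays are independent. For cTEC against mTEC, 3 of 100 splits gave as many as the real 1978, the highest other giving 2285. These splits mix the epithelial populations in the same way, so no conclusion on chance is drawn there either.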

How the results depend on the processing

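The fit without fibroblast arrays was chosen only after the results were seen. The limits are the 2 arrays per group, the dim genes left out, and 3′ bias and thymocyte RNA that moved with age. Of 453 values for named genes, 453 kept their direction and call with the replicate number as a fixed block, 452 without the intensity trend, 449 with equal medians, 449 with no filter, 446 with quantile normalization, 446 with a random block, 444 with a robust variance model, 439 with array weights, 433 with the mean of probe sets and 381 without the least favourable array; 283 of 324 kept it with only the groups compared, 232 of 256 with the 3′ minus 5′ and 231 of 256 with the thymocyte covariate, only 45 of 67 with arrays averaged per age and replicate number, and 0 reversed. The named genes had been chosen as called, with large changes and many without overlap of the arrays compared. That choice favours keeping direction and call, so these numbers do not carry over to all genes called. Equal medians moved the median change of all genes from 1 to 6 months by 0.17 in fibroblasts, where extracellular matrix genes then averaged −2.47, and quantile normalization moved it by 0.142. For fibroblasts against the other 5 populations in that change the shifts were 0.146 and 0.104. Against the other populations, equal medians moved the median by −0.108 in cTEC, −0.113 in mTEClo, 0.197 in Sirpa− DC and 0.106 in Sirpa+ DC, and quantile normalization by −0.115 in mTEChi and 0.135 in Sirpa− DC.

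Where not stated, the cause of a move was not tested. Counts of genes called from 1 to 3 months in mTEChi (0 by limma, with 385 at an unadjusted p under 0.05) were 3 with no filter, 2 with the mean of probe sets, 7 with quantile normalization, 1 with equal medians, 9 with array weights and 3 with only the groups compared. In Sirpa− DC from 1 to 3 months (5) they were 12 with the mean of probe sets, 9 with quantile normalization, 29 with array weights, and 3 with only the groups compared or the thymocyte covariate. The mean of probe sets gave 276 and 737 from 1 to 6 months in Sirpa− and Sirpa+ DC. Array weights gave 19 in Sirpa+ DC from 1 to 3 months, and from 1 to 6 months 2783 in mTEClo, 119 in mTEChi, 1520 in Sirpa− DC, 1703 in Sirpa+ DC, 3172 in fibroblasts and 630 for epithelium against DC. The SD of the difference between the 2 arrays at 6 months was 0.598 in mTEChi and 0.619 in fibroblasts, but 0.243 in Sirpa− and 0.235 in Sirpa+ DC. The main fit takes 1 spread per gene for all groups, so its counts within populations cannot be compared with each other. With only the groups compared there were fewer samples in the fit, with the spread taken from those groups alone, and counts moved both ways. They were 411 in cTEC and 1213 in fibroblasts from 1 to 3 months. From 1 to 6 months they were 229 in cTEC, 2005 in mTEClo, 14 in mTEChi (4 up, 10 down), 1230 in Sirpa− DC, 1267 in Sirpa+ DC and 463 for epithelium against DC. In fibroblasts limma then called 0, with 4346 at an unadjusted p under 0.05.

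Whether the replicate numbers pair the samples stays open: of 45 pairs of populations within an age, 17 had a correlation of residuals over 0.1, 10 of them at 3 months, with a range from −0.068 to 0.418, and the consensus correlation was 0.056. As a random block, age and replicate number gave 278 genes from 1 to 3 months in the mean of the 6 populations. With arrays averaged per age and replicate number in that block, the mean of the 6 populations gave 13 genes from 1 to 3, 1887 from 3 to 6 and 2692 from 1 to 6 months, with fewer samples in the fit.

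With the thymocyte covariate the counts were 117 in cTEC, 161 in mTEClo and 1894 in fibroblasts from 1 to 3 months, 217 in Sirpa− DC, 517 in Sirpa+ DC and 1596 in fibroblasts from 1 to 6 months, and 947 for the interaction. With the 3′ minus 5′ covariate they were 409 in cTEC and 1864 in fibroblasts from 1 to 3 months, 567 in cTEC, 382 in mTEClo, 71 in Sirpa− DC and 2697 in fibroblasts from 1 to 6 months, and in the mean of the 6 populations 134 from 1 to 3 and 1575 from 1 to 6 months. The higher fold threshold, by construction, gave 468 in cTEC, 500 in mTEClo, 833 in mTEChi, 265 in Sirpa− DC, 348 in Sirpa+ DC and 368 in fibroblasts, 855 for mTEChi against mTEClo, 478 for cTEC against mTEC and 213 between DC populations. For ages it gave 452 in cTEC and 1473 in fibroblasts from 1 to 3 months, 586 in cTEC, 562 in mTEClo, 503 in mTEChi, 187 in Sirpa+ DC and 2645 in fibroblasts from 1 to 6 months, and 22, 113 and 136 in the mean of the 6 populations for 3 against 1, 6 against 3 and 6 against 1 month. With an estimated correlation the mean changes were unaltered by construction, but the E2F targets in the epithelial mean (−0.52, adjusted p = 0.43) and the inflammatory mediators in the DC mean (0.38, adjusted p = 0.299) were no longer called. With only the groups compared the Aire-dependent antigens in mTEChi (0.511) were called, adjusted p = 0.00332, but not with an estimated correlation (adjusted p = 0.786). Without fibroblast arrays the E2F targets in the mean of the populations were called (−0.313, adjusted p = 5.61e-05), but not with an estimated correlation (adjusted p = 0.58).

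With 1 array left out, where a lone array is assumed to vary like the other groups, counts ranged from 1373 to 1472 in cTEC, 1296 to 1449 in mTEClo, 1981 to 2066 in mTEChi, 892 to 934 in Sirpa− DC, 960 to 995 in Sirpa+ DC and 1173 to 1275 in fibroblasts, 2780 to 2961 for mTEChi against mTEClo, 1933 to 2039 for cTEC against mTEC and 738 to 837 between DC populations. From 1 to 3 months they ranged from 138 to 939 in cTEC, 63 to 380 in mTEClo, 0 to 6 in mTEChi, 3 to 22 in Sirpa− DC, 20 to 66 in Sirpa+ DC, 1060 to 3352 in fibroblasts and 437 to 1257 in the mean. From 1 to 6 months they ranged from 299 to 1205 in cTEC, 348 to 1177 in mTEClo, 603 to 2732 in mTEChi, 16 to 212 in Sirpa− DC, 23 to 601 in Sirpa+ DC, 2147 to 5702 in fibroblasts, 4753 to 5702 in the mean, and 3984 to 4980 there from 3 to 6 months. They ranged from 144 to 836 for epithelium against DC and from 1237 to 4070 for the interaction. The list means ranged from −0.16 to −0.121 (E2F, mean of 6), −0.559 to −0.48 (E2F, epithelium), 0.335 to 0.426 (inflammatory, DC) and 0.421 to 0.602 (Aire-dependent, mTEChi).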

Other observations

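No test was run for this part after the results were seen. Further gene groups set the medullary populations apart. Of 9 tuft-like cell markers, 6 were higher in mTEClo than in the other 5 populations and 0 lower (mean log2 1.22; camera adjusted p = 0.0209, and 0.388 with an estimated correlation), with the kinase Dclk1 at 3.09 ± 0.23 and the taste channel Trpm5 at 2.42 ± 0.29 (SE, n = 6 against 30). Of 11 genes of keratinised epithelium, 9 were higher in mTEChi and 0 lower (mean 2.44; adjusted p = 5.69e-06, and 0.0242 with an estimated correlation), such as the antibody transporter Pigr (4.79 ± 0.30) and the cornified envelope gene Sprr1a (3.90 ± 0.19). Of 8 granulocyte markers, 6 were higher in mTEChi and 0 lower (mean 2.57; adjusted p = 0.00511, and 0.194 with an estimated correlation), with S100a8 at 5.70 ± 0.32, S100a9 at 3.78 ± 0.16 and the peroxidase Mpo at 3.56 ± 0.10. The counts adjusted over the list alone were the same.

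Single immunoglobulin transcripts rose with age in some comparisons, and no list of such genes was tested. In cTEC, Igkv15-103 rose by log2 3.01 ± 0.78 (SE, n = 2 arrays per age) from 1 to 3 months and by 4.59 ± 0.78 from 1 to 6 months, with an SD of 2.456 between the arrays at 1 month. In mTEChi Ighm rose by 3.42 ± 0.99 from 1 to 6 months, with the same sign in 6 of 9 probe sets. The B cell markers were not called as a list there: their mean change was 0.037 (camera adjusted p = 0.534) and 0.274 (adjusted p = 0.527) in cTEC from 1 to 3 and from 1 to 6 months, and 0.358 (adjusted p = 0.796) in mTEChi from 1 to 6 months. In the mean of the 6 populations Jchain rose by 2.16 ± 0.66 and Igha by 1.85 ± 0.56 from 1 to 3 months. The GTPase Gbp2b rose by 0.99 ± 0.14 and the chemokine Cxcl9 by 1.29 ± 0.19 in that comparison, and Gbp2b fell by 1.17 ± 0.14 from 3 to 6 months.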
